A study of Mus musculus with 2 samples.

How the data were processed

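Droplet-based single-cell RNA-seq libraries were made from immune cells sorted by flow cytometry out of MC38 tumours, which grow from a mouse colon carcinoma line, on day 21. The series has 1 group of 2 replicate libraries, numbered as in the labels. The names of the deposited files carry a different word for each library that the labels do not explain. These words were not used, so every SD and p-value rests on the labels' statement that the libraries are replicates of 1 group. Nothing in the labels says that the replicates came from separate animals. Phagocytes of replicate 1 held 1269 Xist and 0 Y-linked UMIs and those of replicate 2 held 0 and 149, so the libraries did not come from 1 and the same animal. Differences shared by a whole library are taken out by fitting the library as a block. Except in fits without the block, every p-value below therefore measures only how far class differences varied between these 2 libraries. The main fit pools this variation over classes, with 5 residual degrees of freedom. In it technical differences, sex and other differences between animals cannot be separated.

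Each deposited file holds raw UMI counts per gene and cell barcode, with no normalisation, per the file headers and the whole-number values. The matrices came from Cell Ranger 6.0.1 per the file headers, and the submitters' processing notes name Cell Ranger 6.0.1, Seurat 4.0.1 and the genome build mm10. What Seurat was used for, and the gene annotation, are not given in the sources used here. The barcode lists hold 2749 and 2937 barcodes, none with under 500 UMIs, over 32285 genes. The libraries total 5688000 and 5862342 UMIs, with a median of 1309 and 1375 UMIs per barcode. At this depth a single UMI in the 139 T and NK cells of replicate 1 is worth 4.13 CPM (UMI counts scaled to a common total), as the Acss2 count there shows, so genes of a few CPM cannot be ranked between cell classes.

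The following choices were made before the data were examined: the cell filters, the clustering settings, the cell type markers, the 16 gene lists, the tests of genes and their block, the main list of alternatives and the rule for named genes. Cells were kept at 300 or more detected genes and under 10% mitochondrial UMIs, which left 2388 and 2837 barcodes. Scrublet, run per library, called 8 and 41 of these doublets, 0.938% over both libraries, and they were left out, so that 2380 and 2796 cells were kept. Only 0.335% of the barcodes of replicate 1 were called, so doublets of unlike cells can remain there. Counts were scaled to 10000 per cell and logged, and both libraries were clustered together with scanpy 1.11.5 and leidenalg 0.10.2 on 2000 variable genes, 30 components and 15 neighbours at resolution 1, with no batch correction. The 12 metabolic and chromatin lists, which hold 306 genes, took no part in the clustering. Over the 16 lists there are 400 distinct genes, and 399 of them are in the files. Clusters were named from the fixed markers by hand, which left room for judgement, and clusters with hardly any RNA of Ptprc, the gene of the leukocyte antigen CD45, and no immune markers were called Ptprc-low after their values were seen. The T and NK cell-like cells were clustered again with 1000 variable genes and 20 components.

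Raw counts were summed per library and class for the 6 named classes with at least 20 cells in both libraries, where macrophage-like and monocyte-like cells were summed as phagocytes. The Ptprc-low cells have no type name and were left out of the fit, although they were numerous in both libraries. The 12 sums were fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr, library as a block), and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. All 6 classes shared 1 estimate of the spread, so the classes with few cells add to it. The classes compared come out of the same library, so the replicate number pairs them by construction. The planned comparison of CD8 T cells with phagocytes was made with the whole T and NK cell-like cluster, because no cluster held CD8 T cells alone. The planned comparisons of terminally exhausted with progenitor exhausted CD8 T cells, and of CD8 with CD4 T cells, were not made, because too few such cells were found. Genes that took part in building the clusters can differ between classes by construction, so results are given for the other genes. Genes expressed along with them can differ for the same reason. Calls of lineage genes therefore describe the classes and are no independent test of them. On simulated counts for the T and NK cell comparison over 2058 genes, the fit recovered 64% of genes changed 2-fold and 92% of genes changed 4-fold, and 4.29% of its calls were false. The simulation gave all classes and libraries the same profile and changed only genes above a minimum mean count. It held no library differences and no phagocyte RNA in the T and NK barcodes, so these rates need not hold for the real data.

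The gene lists were acetyl-CoA supply, histone acetyltransferases, histone deacetylases and sirtuins, acetyl-lysine readers, histone and DNA methylation enzymes, glycolysis, TCA cycle, oxidative phosphorylation, sterol synthesis and SREBP, fatty acid synthesis, uptake and oxidation, amino acid transport and mTORC1 control, hypoxia response, interferon-stimulated genes, dissociation stress, and the S and G2/M phases of the cell cycle. Lists with at least 3 tested genes were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and with fry. These list tests were planned for the comparison of exhausted states and were applied to T and NK cells after the data were seen.

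By the rule for named genes, Acss2, Acly, Kat2a, Ep300 and Slc16a1 are always given, as is the gene with the smallest unadjusted p of each metabolic or chromatin list among those with at least 20 CPM in a class. Clusters are described by the 5 genes with the highest fold over other clusters among those detected in at least 25% of their cells. The 6 largest rises and 6 largest falls were taken among called genes outside the clustering genes, at a mean of at least 50 CPM in the higher class. These genes also had to change in the same direction in both libraries. Ribosomal protein, mitochondrial, T cell receptor and immunoglobulin genes were left out. This rule was planned for the comparison of exhausted states and was applied to T and NK cells after the data were seen. Some genes that these rules name are not reported here. Any other gene named was chosen after its values were seen.

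Shares of cells carry exact Clopper-Pearson 95% intervals and CPM of summed counts carry exact Poisson intervals, and both cover counting error only. A count of 0 is given the limit of 3 counts. To compare shares of cells with a UMI across depths, cells were also thinned to 800 UMIs. Alternatives were DESeq2 size factors, the Wald test of DESeq2 1.42.0, no filter on low counts, no block, looser and stricter cell filters, barcodes with RNA of both lineages left out, cells thinned to 1500 UMIs, leaving out each replicate, ComBat by library, other resolutions and, added after seeing the data, 5 further settings of the gene tests. Gene positions are from GENCODE vM21 on GRCm38, 1-based, and are those of whole gene bodies. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.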

Results

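Immune cells sorted from MC38 tumours, grown from a mouse colon carcinoma line and taken on day 21, were profiled by single-cell RNA-seq in 2 replicate libraries. Replicate 1 held 5688000 UMIs and replicate 2 held 5862342 UMIs, and 2380 and 2796 cells were kept. The kept cells had a median of 1491.5 and 1378.5 UMIs. The series title concerns nutrients, histone marks and the fates of exhausted CD8 T cells, so T cells and the genes of acetyl-CoA supply and histone acetylation are described most closely. The labels give no second group, so the comparisons below are between cell classes of the same libraries.

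Macrophage-like cells, with C1qa, Apoe and Csf1r among their markers, made up 41.8% ± 9.80 of kept cells (SD, n = 2). They were the most frequent class in replicate 1 (48.7%), while in replicate 2 (34.8%) cells nearly without Ptprc RNA were more frequent (36.4%). T and NK cell-like cells, led by Gzmb, Nkg7, Il2rb, Ms4a4b and Cd3d, made up 11.3% ± 7.78. Their share was 5.84% in replicate 1 (139 cells, 95% interval 4.93 to 6.86) and 16.8% in replicate 2 (471 cells, 15.5 to 18.3). Type 2 dendritic cell-like cells stood at 4.30% ± 2.54, neutrophil-like cells, led by S100a9 and S100a8, at 3.14% ± 2.95, and type 1 dendritic cell-like cells, led by Xcr1, at 2.61% ± 3.44. Monocyte-like cells with Chil3 (1.15% ± 0.458), plasmacytoid dendritic cell-like cells with Siglech (1.02% ± 0.280), mature migratory dendritic cell-like cells with Ccr7 and Ccl22 (0.969% ± 0.0555) and fibroblast-like cells with Col1a1 (0.757% ± 0.952) were rarer. The cells nearly without Ptprc RNA, called Ptprc-low, made up 33.0% ± 4.89 over both libraries, although the labels describe a sort for immune cells. The intervals of the 2 libraries did not overlap for macrophage-like, neutrophil-like, T and NK cell-like, type 1 and type 2 dendritic cell-like, fibroblast-like and Ptprc-low cells, so these shares differed between replicates by more than counting error.

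**Figure D1:**
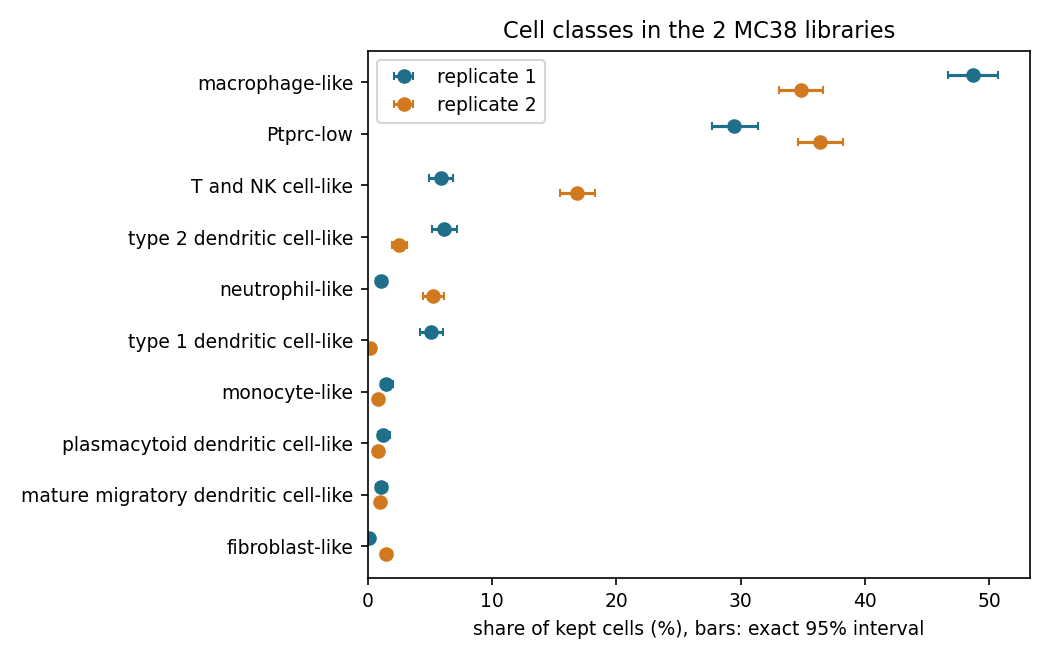
Share of each cell class among kept cells (x axis, percent) in replicate 1 and replicate 2, with exact 95% intervals as bars. T and NK cell-like cells stand at 5.84% and 16.8%, and macrophage-like cells at 48.7% and 34.8%.

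The macrophage-like class came from different clusters in the libraries. A cluster led by Ly6i, Il1b, Fcgr4, Clec4n and Cxcl9 held 879 cells of replicate 2 and 9 of replicate 1. Clusters led by Lyz2, Xist, Apoe and Trem2 (562 and 50 cells) and by Fcrls, Lyz2, Apoe, Trem2 and Stab1 (487 and 31 cells) were mostly of replicate 1. The Ly6i cluster had none of the macrophage markers among its top 10 genes and 1 marker of type 2 dendritic cells, Itgax, and the type 2 dendritic cell-like cluster, led by Mgl2 and Napsa, had none of its own there and 1 monocyte marker, Ccr2, so the names of both clusters are uncertain. The Ly6i cluster held 879 of the 974 macrophage-like cells of replicate 2. ComBat by library aligns the libraries before clustering. Its clusters were named by rule from scores of the fixed markers and the Ptprc level, not by hand. The mean share of macrophage-like cells was then 28.3%, below the 33.0% of Ptprc-low cells, and that of type 2 dendritic cell-like cells was 8.16%. T and NK cell-like cells then made up 18.1% ± 8.25 and neutrophil-like cells 1.93% ± 0.710, each over 1.5 times from the share without ComBat though within 1 SD of it. Of the cells in 1 of the 2 ComBat clusters named T and NK cell-like, 33.2% had that name without ComBat. In the ComBat clusters named monocyte-like and type 2 dendritic cell-like, 20.8% and 46.4% of cells had the same name without ComBat. The changes in share can come from the way of naming as well as from the alignment, which were not separated.

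Exhausted CD8 T cells could not be resolved into progenitor and terminal states. Cd8a, which encodes a CD8 chain, stood at 86.7 CPM (53.7 to 133) in the T and NK cells of replicate 1 and at 229.7 CPM (198 to 265) in those of replicate 2. A UMI of Cd8a or Cd8b1 was found in 20 of 139 and 203 of 471 of these cells. Cd8a alone had a UMI in 11.5% and 28.9% of them and in 0.838% and 2.51% of phagocytes, or 4.24% and 15.9% against 0.222% and 1.97% in cells thinned to 800 UMIs. Pdcd1, the gene of the inhibitory receptor PD-1, stood at 16.5 CPM (4.50 to 42.3) and 111 CPM (89.2 to 137), and Tox, a transcription factor of exhausted cells, at 24.8 CPM (9.09 to 53.9) and 19.98 CPM (11.4 to 32.4). Havcr2, which encodes the terminal marker TIM-3, had a UMI in 7.91% and 8.92% of T and NK cells, and in 5.78% and 5.72% of phagocytes. Slamf6, a progenitor marker, had a UMI in 1.44% and 3.18% of T and NK cells and in 2.76% and 3.11% of phagocytes, so its share in T and NK cells could not be told from that of phagocytes. Tcf7, the transcription factor of progenitor cells, had a UMI in 1.44% and 1.06% of T and NK cells against 0.168% and 0.201% of phagocytes. Ptprc-low cells, which were deeper, had a Tcf7 UMI in 0.570% and 1.96% of cells, so the Tcf7 share of T and NK cells did not stand above that of every other class in replicate 2. Their shares were 0.285% and 0.295% for Havcr2, 0.142% and 0.196% for Slamf6 and 0.142% and 0.589% for Cd8a. Median depths were 1411 and 1328 UMIs in T and NK cells, 1260.5 and 1057 in phagocytes and 2056 and 2274.5 in Ptprc-low cells. Thinned to 800 UMIs, which kept 118 and 396 T and NK cells and 900 and 760 phagocytes, the shares for Havcr2 were 4.24% and 5.56% against 2.56% and 3.03%, those for Slamf6 0.847% and 1.01% against 0.556% and 2.37%, and those for Tcf7 0.847% and 0.758% against 0.222% and 0.263%, with 0.308% and 0.517% in 649 and 967 Ptprc-low cells.

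A gate of Tcf7 or Slamf6 without Havcr2 held 4 and 15 T and NK cells, of which 1 and 7 also had a Cd8a or Cd8b1 UMI, and the opposite gate held 11 and 38, of which 1 and 20 did. Cd4 had a UMI in 3 and 4 T and NK cells and in 10 and 9 phagocytes. Clustering the T and NK cells again gave 7 groups, of which 1, led by Lyz2, Xist, Xcl1, Apoe and Trem2, had 20 or more cells in both libraries. C1qa stood at 111 CPM in the group led by Gzmc, with a UMI in 9.86% of its cells. In groups mostly of replicate 2 it ran from 581 CPM (21.7% of cells, led by Ctsl) to 2435 CPM (81.8%, led by Ccl8). Phagocyte RNA was thus uneven over these groups, which were formed on expression. No comparison of exhausted states, or of CD8 with CD4 T cells, was made from so few cells.

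T and NK cells held more RNA of Lck, Gimap5, Sept1, Sh2d2a, Gimap6 and Ptpn22 than phagocytes, the macrophage-like and monocyte-like cells of the same libraries. Lck, the kinase that starts signalling at the T cell receptor (ENSMUSG00000000409, chromosome 4, 129548344 to 129573641, minus strand), stood at 119 ± 24.9 CPM against 11.7 ± 4.77 (SD, n = 2), a log2 fold change of 3.36 (SE 0.44, edgeR adjusted p = 2.23e-05). Gimap5 and Gimap6, GTPases of lymphocytes, rose by 3.17 (SE 0.48) and 2.60 (SE 0.48), and Sh2d2a, a T cell adaptor, by 2.75 (SE 0.47). Sept1, which encodes a septin, rose by 3.15 (SE 0.48), and Ptpn22, a phosphatase of antigen receptor signalling, by 1.72 (SE 0.42). On the phagocyte side, Axl, a receptor tyrosine kinase of apoptotic cell uptake, stood at 56.8 ± 4.42 CPM in T and NK cells against 139.5 ± 1.76 in phagocytes, a log2 fold change of -1.19 (SE 0.28, edgeR adjusted p = 0.0127).

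Mpeg1, which encodes a pore-forming protein of macrophages, fell by 1.03 on the log2 scale (edgeR adjusted p = 0.00506), the tetraspanin gene Cd63 fell by 0.99, and Mfsd1, a lysosomal membrane transporter, fell by 1.15. Dab2, an endocytic adaptor, and Asah1, the lysosomal acid ceramidase, fell by 1.10 and 0.97. The changes of Dab2, Asah1 and Mfsd1 differed between libraries. Without replicate 2 the log2 fold change was -2.06 for Dab2, -2.32 for Asah1 and -2.16 for Mfsd1, and without replicate 1 it was -0.60, -0.61 and -0.98. In DESeq2's Wald test Mpeg1 was the 1 fall of these 6 that passed (adjusted p = 0.00635), with DESeq2 adjusted p of 0.178 for Axl, 0.154 for Mfsd1, 0.210 for Cd63, 0.255 for Asah1 and 0.345 for Dab2, and Ptpn22 was the 1 rise of 6 that did not (0.0897). Named after their values were seen, Cd82, Hcst, Odc1, Rac2 and Tmsb10 were also higher in T and NK cells in edgeR, and Cd68, Aif1, Lgmn, Lamp1, Ctsz and Trem2 were lower. Outside the clustering genes, DESeq2's Wald test called only 2 genes lower, Mpeg1 among them, and the fit without the block 0. Trem2 stood at 165 against 553 CPM in replicate 1 and at 96.1 against 117 CPM in replicate 2. Cd68 is among the fixed macrophage markers by which clusters were named, so its fall follows in part from the naming. Phagocyte RNA was present in the T and NK barcodes, whose C1qa, C1qb and C1qc level was 35.6% of that of phagocytes in replicate 1 and 64.0% in replicate 2, and the T and NK cells are compared with phagocytes mostly from the Lyz2 and Fcrls clusters in replicate 1 and from the Ly6i cluster, whose name is uncertain, in replicate 2. With the phagocyte profile subtracted at the share set by C1q, a setting added after the data were seen that gives no test, the 6 rises ran from 2.46 for Ptpn22 to 4.23 for Lck and the 6 falls from -5.66 for Axl to -7.92 for Mpeg1. Subtracted levels stop at 0 and 1 CPM was added, so the size of these falls depends on that floor. With barcodes of both lineages left out, which kept 21 of 139 and 31 of 471 T and NK cells and selects them for a lack of phagocyte RNA, Mpeg1 stood at -2.78, Dab2 at -2.96 and Cd63 at -1.80, and the other 9 of these 12 genes were not tested.

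Of the 2011 tested genes that took no part in clustering, edgeR called 25 higher and 20 lower in T and NK cells, 45 in all, and 261 had an unadjusted p under 0.05. Fewer genes were called without the block by replicate, where Lck, Gimap5 and Sept1 were higher and 0 genes lower (53 at an unadjusted p under 0.05). DESeq2's Wald test called 22 higher and 2 lower, 24 in all, of which 14 were among the 45, and the T and NK cells with a Cd8a or Cd8b1 UMI had 6 higher and 2 lower. More were called with no filter on low counts (84 higher, 12 lower), with only these 2 classes in the fit (114 and 76) and with barcodes that held RNA of both lineages left out (39 and 70), where lower calls of phagocyte genes follow in part from the selection.

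No tested gene of metabolism or chromatin passed between T and NK cells and phagocytes. Of the 306 listed genes 130 were tested, and 0 passed in edgeR, where 4 had an unadjusted p under 0.05. DESeq2's Wald test also called 0, with 1 at an unadjusted p under 0.05. Slc43a2, a transporter of large neutral amino acids (41.5 ± 29.5 CPM against 88.0 ± 30.5), had a log2 fold change of -1.03 (SE 0.31, edgeR adjusted p = 0.0557), or -1.64 without replicate 2 and -0.80 without replicate 1. It was the 1 metabolic or chromatin gene that passed when adjusted over the list alone, among 5 tested genes of amino acid transport and mTORC1 control. With barcodes of both lineages left out, 1 listed gene passed, Cox6c, which was higher. With only these 2 classes in the fit, 3 passed, Kmt2a higher and Rragc and Slc43a2 lower. That fit leaves 1 residual degree of freedom, against 5 in the main fit. The T and NK barcodes held C1q RNA at 35.6% and 64.0% of the phagocyte level, and with the phagocyte profile subtracted, again with no test, Slc43a2 stood at -6.43, Kdm6b at -5.39, Slc25a1 at -3.57, Fabp5 at -3.42, Gpi1 at -0.94, Hif1a at 1.01 and Uqcrfs1 at 0.77. Here too subtracted levels stop at 0 and 1 CPM was added, so the size of the large falls depends on that floor.

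The carbon metabolism lists had medians near 0. The 71 tested genes of oxidative phosphorylation had a median log2 fold change of 0.04, the 14 of glycolysis -0.11 and the 11 of the TCA cycle -0.13. Slc25a1, the mitochondrial citrate carrier that exports the substrate of Acly, stood at 25.5 ± 1.02 CPM against 44.6 ± 0.339, a log2 fold change of -0.84 (SE 0.51, edgeR adjusted p = 0.415), among 7 tested genes of acetyl-CoA supply with a median of -0.12. Hif1a, among 11 hypoxia response genes, had a log2 fold change of 0.60 (edgeR adjusted p = 0.174), Uqcrfs1 of respiratory complex III 0.49 (0.242) and the glycolytic isomerase Gpi1 -0.35 (0.420). Among 8 fatty acid genes the lipid carrier Fabp5 had -0.69 (edgeR adjusted p = 0.256), and among 4 sterol genes the transcription factor Srebf2 had 0.44 (0.565). Among the chromatin lists, 5 acetyl-lysine readers were tested, with Baz1a at 0.42 (edgeR adjusted p = 0.544), 1 deacetylase, Hdac1, at 0.38 (0.671), 2 methylation enzymes, with Kdm6b, a histone demethylase, at -0.84 (0.330), and 0 acetyltransferases. Without replicate 2 Kdm6b stood at -2.01, Fabp5 at -1.43, Gpi1 at -0.65, Srebf2 at 0.22 and Hdac1 at 0.25, and without replicate 1 they stood at -0.71, -0.38, -0.20, 0.45 and 0.43. The direction of Baz1a differed between libraries, at -0.021 without replicate 2 and 0.52 without replicate 1. With barcodes of both lineages left out Hif1a stood at 1.43 (edgeR adjusted p = 0.0602) and Fabp5 at -1.67 (0.131). Under the stricter cell filter Hif1a stood at 0.35, and Kdm6b stood at -1.60 in cells thinned to 1500 UMIs.

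Of the cell cycle genes tested, 1 of each phase rose in T and NK cells. Dut, which keeps uracil out of DNA, rose by 1.36 (SE 0.31, edgeR adjusted p = 0.0107) among 3 tested S phase genes, and Hmgb2, a chromatin protein that was also a clustering gene, rose by 0.94 (SE 0.21, edgeR adjusted p = 0.00759) among 5 tested G2/M genes. Adjusted over the list alone, 1 S phase gene and 3 G2/M genes, Hmgb2, Ube2c and Top2a, were higher. Among 12 interferon-stimulated genes 0 passed over all genes in edgeR, and Ifi204 was lower when adjusted over the list alone. Its log2 fold change was -0.90 with an edgeR adjusted p of 0.0503. Among 19 dissociation stress genes 0 passed in edgeR. In limma's camera, applied to these classes after the data were seen, 0 lists passed at the preset correlation or with an estimated correlation, and 0 passed in fry. The smallest adjusted p was 0.221, for G2/M genes (adjusted p = 0.767 with an estimated correlation), and that of oxidative phosphorylation was 0.513. The sterol, fatty acid and dissociation stress lists had a positive median and mean but a downward camera direction, and hypoxia response pointed up in camera and down in fry.

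**Figure D2:**
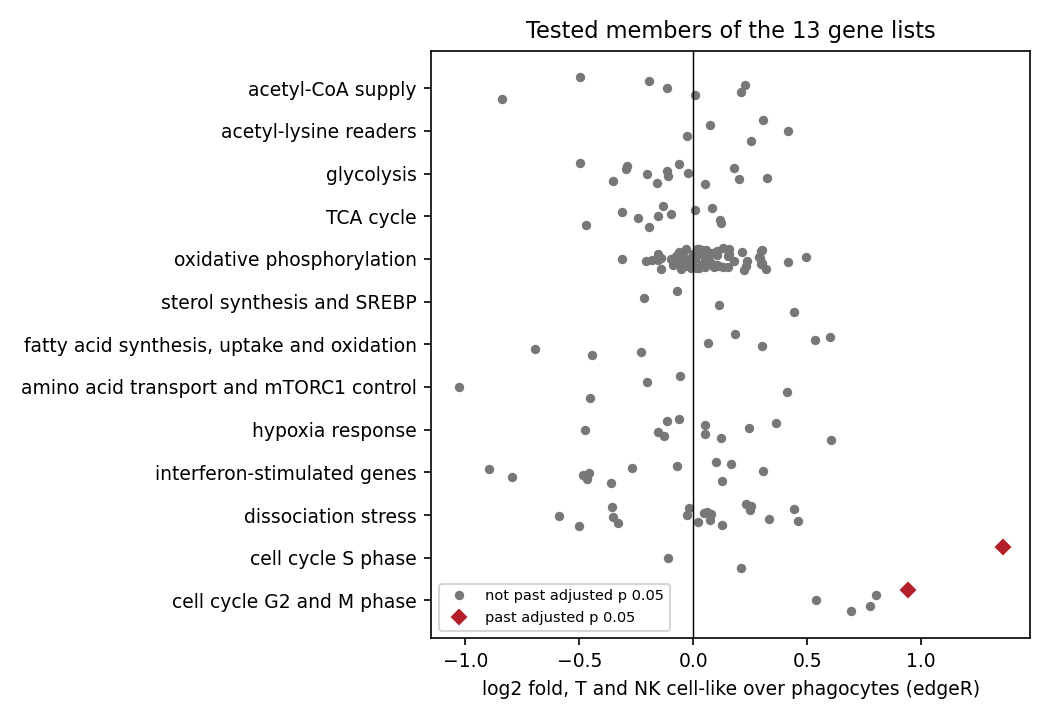
Log2 fold change of each tested list gene, T and NK cells over phagocytes (x axis, edgeR), with 1 row per gene list and dots spread vertically for legibility. Red diamonds mark the 2 genes past the adjusted p threshold, Dut and Hmgb2, and grey dots the rest.

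Acly, Acss2, Kat2a, Ep300 and Slc16a1 did not pass the planned filter, which ran over all 6 classes, and are given from the fit with no filter. Acly, which makes acetyl-CoA from citrate (ENSMUSG00000020917, chromosome 11, 100476353 to 100528000, minus strand), stood at 62.6 ± 10.8 CPM in T and NK cells and 48.5 ± 17.5 in phagocytes (SD, n = 2), a log2 fold change of 0.29 (SE 0.34). In replicate 1 it was 70.2 (40.9 to 112) against 36.2 CPM (28.6 to 45.1), and in replicate 2 it was 54.9 (39.9 to 73.8) against 60.9 CPM (48.3 to 75.8), so the direction differed between libraries. Acss2, which makes acetyl-CoA from acetate (ENSMUSG00000027605, chromosome 2, 155517948 to 155585724, plus strand), stood at 5.81 ± 2.38 against 3.35 ± 0.438 CPM, from 1 and 6 UMIs in T and NK cells, and its difference was not detectable at this depth. The acetyltransferase genes Kat2a (ENSMUSG00000020918, chromosome 11, 100704746 to 100712465, minus strand) and Ep300 (ENSMUSG00000055024, chromosome 15, 81585351 to 81652077, plus strand) stood at 24.6 ± 11.9 against 12.03 ± 3.42 CPM and at 49.3 ± 6.18 against 38.3 ± 11.5 CPM. Slc16a1, a monocarboxylate transporter (ENSMUSG00000032902, chromosome 3, 104638668 to 104658462, plus strand), stood at 11.8 ± 0.815 against 4.19 ± 2.69 CPM, from 3 and 9 UMIs in T and NK cells. Log2 fold changes were 0.92 (SE 0.96) for Acss2, 0.79 (SE 0.52) for Kat2a, 0.27 (SE 0.36) for Ep300 and 1.24 (SE 0.80) for Slc16a1. The libraries differed, since Kat2a stood at 1.68 without replicate 2 and 0.16 without replicate 1, Slc16a1 at 2.03 and 0.79, and Acss2 at 0.14 and 1.07. Ep300 changed sign, at 0.81 without replicate 2 and -0.045 without replicate 1, and in cells thinned to 1500 UMIs it stood at -0.27 and Acly at -0.34. With the phagocyte profile subtracted Slc16a1 stood at 2.04 and Kat2a at 1.25. None of the 5 passed in edgeR, with adjusted p between 0.952 and 0.992. Scap, a sterol-sensing escort of the SREBP transcription factors, stood at 12.4 CPM (2.55 to 36.2) and 8.74 CPM (3.51 to 18.0) in T and NK cells and at 7.32 CPM (4.19 to 11.9) and 9.13 CPM (4.72 to 15.9) in phagocytes.

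**Figure D3:**
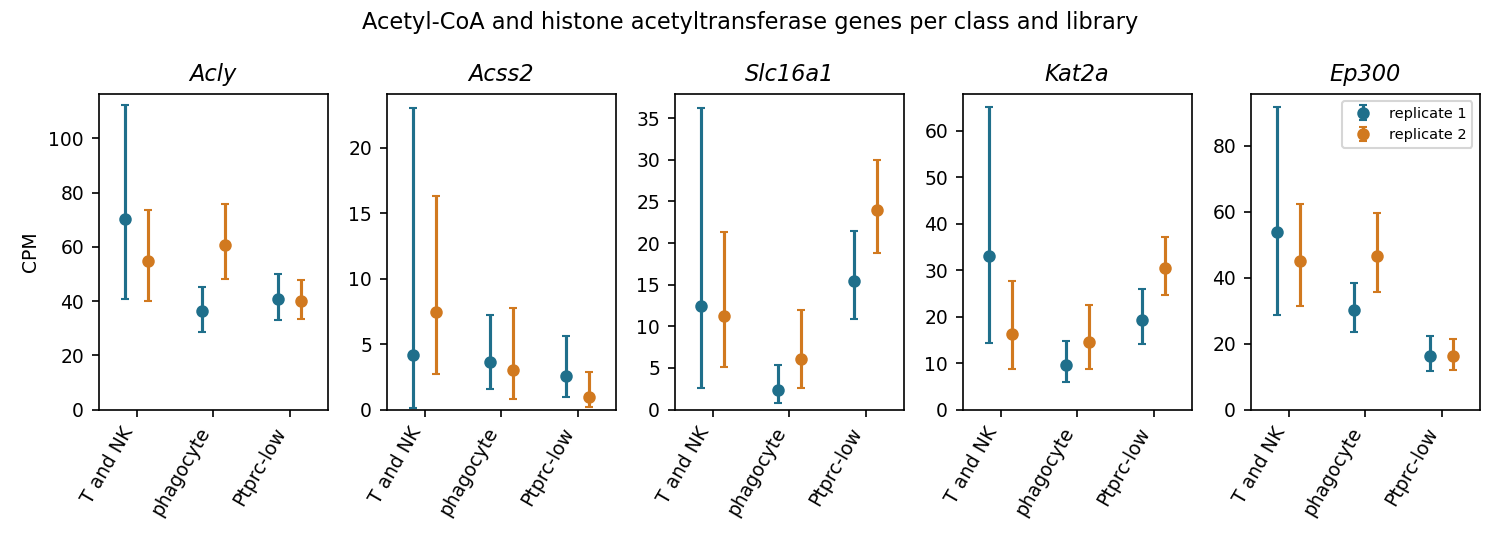
CPM (y axis, a separate linear scale per gene) of 5 acetyl-CoA and histone acetyltransferase genes in T and NK cells, phagocytes and Ptprc-low cells of each library, with exact Poisson 95% intervals as bars. For Acly the T and NK cells stand above phagocytes in replicate 1 (70.2 against 36.2 CPM) and below in replicate 2 (54.9 against 60.9 CPM), with overlapping intervals in both libraries.

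The replicate libraries had correlated profiles of phagocytes, T and NK cells and Ptprc-low cells. Across 6914 genes the phagocyte profiles had a Pearson r of 0.916 and a Spearman rho of 0.869 on log2 CPM, the T and NK cells 0.832 and 0.760, and the Ptprc-low cells 0.816 and 0.739, where genes are not independent replicates. The classes with fewer cells (23 to 146 per library) correlated less over genes with a mean of 10 CPM or more, at a Pearson r of 0.130 for monocyte-like, 0.183 for plasmacytoid, 0.244 for mature migratory dendritic, 0.378 for neutrophil-like and 0.602 for type 2 dendritic cell-like cells. Over genes detected in both libraries it lay between 0.796 and 0.843 for these 5 classes. Phagocytes of replicate 1 held more RNA of Lyz2, a lysozyme gene (7168 against 28.1 CPM), Pmepa1 (249 against 23.6) and Cxcl14, a chemokine (93.9 against 3.04). Those of replicate 2 held more RNA of the inflammatory genes Il1b (731 against 44.4), Ptgs2 (161 against 5.49) and Thbs1 (305 against 28.4) and of the interferon-inducible gene Ifitm1 (1294 against 145). Of 2548 genes over 50 CPM in phagocytes, 18 differed over 8-fold, and of 2370 in Ptprc-low cells, 64 did. In the small classes 1541 of 4373 did in monocyte-like cells, 769 of 3662 in plasmacytoid, 547 of 3140 in mature migratory dendritic, 277 of 2749 in neutrophil-like and 53 of 2705 in type 2 dendritic cell-like cells. The genes named here were chosen after their values were seen. The chi-square of the phagocyte counts was 23.9 per degree of freedom, more than counting error gives, so the libraries were not 1 library deposited again. It does not tell separate captures of 1 suspension from separate samples, which the Xist and Y-linked UMIs do.

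**Figure D4:**
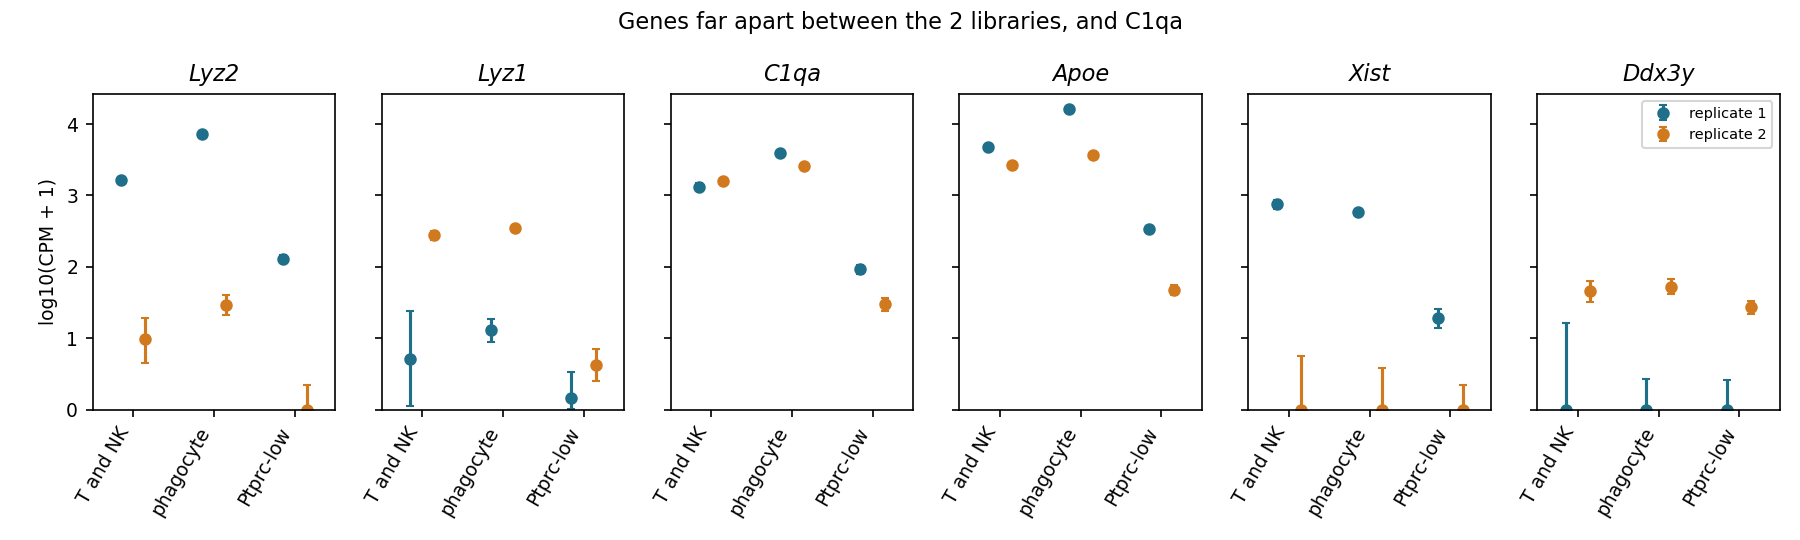
Level of 6 genes (y axis, log10 of CPM plus 1, bars exact Poisson 95% intervals) in T and NK cells, phagocytes and Ptprc-low cells of each library. Lyz2 in phagocytes stands at 7168 CPM in replicate 1 and 28.1 CPM in replicate 2, and C1qa is present in T and NK barcodes of both.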

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

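In this part, the tests of fibroblasts and of immune cell RNA were chosen only after the result was seen. Ptprc-low cells made up 29.5% of kept cells in replicate 1 and 36.4% in replicate 2, a large signal in sorted immune cells that no planned comparison uses. In replicate 2 these cells held 35.2 CPM of Y-linked RNA (28.9 to 42.5), above the limit of 0.970 CPM that a count of 0 allows. In replicate 1 they held 0 Y-linked UMIs, with a limit of 1.29 CPM. Their Xist RNA stood at 18.04 CPM there, against 581 CPM in phagocytes, and their C1q RNA at 2.39% of the phagocyte level.

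The Ptprc-low cells split almost completely by library. Those of replicate 1 were led by Dcn and Rhox5 (606 and 401 CPM, against 52.4 and 31.4 in replicate 2), and those of replicate 2 by Nefl and Grem1 in a cluster of 850 cells and by Mgp in a cluster of 160. Crabp1 (1095 against 2.15 CPM), Lgals7 (737 against 3.01), Spp1 (1478 against 56.7) and Hmga2 (562 against 53.3) were also higher in replicate 2. Of the tumour or epithelial markers, Epcam had 0 UMIs in both libraries, with limits of 1.29 and 0.970 CPM, Krt8 had 0 and 1 UMIs and Krt18 had 0 and 3.

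Tested for a difference of the whole libraries, the 23 genes over 8-fold apart in Ptprc-low cells that phagocytes also express had a median log2 fold change there of 0.86 in the same direction (quartiles -0.42 to 1.25), so such a difference does not account for all of it and may account for part. Fibroblasts like those of the fibroblast-like cluster were argued against as the bulk of these cells by the 5 fibroblast markers, whose median was 4.83% of the fibroblast-like level in replicate 1 and 2.68% in replicate 2, with Col1a1 at 0.0673% and 0.0675% and Col1a2 at 0.00369% and 3.53%. Dcn at 31.1% in replicate 1, where it leads a cluster, and Pdgfra at 14.2% and 22.3% stood apart from the other markers, so fibroblasts of another kind, or as a minority, stay open. Carried-over immune RNA was argued against as the source of the Y-linked RNA of replicate 2. That RNA stood at 31.1% of the phagocyte level where C1q RNA stood at 0.985%. Carried-over RNA as the source of the Xist UMIs of replicate 1 was not tested. What these cells are stays open, tumour cells among the possibilities, and no biological explanation was tested because the labels give 1 group.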

How the results depend on the processing

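In this part, the settings limited to cells with a Cd8a or Cd8b1 UMI, to 2 classes, to macrophage-like cells, without ribosomal RNA-like genes and with the phagocyte profile subtracted were chosen only after the result was seen. The count of 45 genes for T and NK cells against phagocytes became 96 with no filter on low counts, 190 with only the 2 classes and 109 with barcodes of both lineages left out, where other numbers of genes were tested (13048, 6612 and 707). It became 8 with cells with a Cd8a or Cd8b1 UMI, where 826 were tested, 3 without the block that pairs classes by replicate and 24 in DESeq2's Wald test, and beyond these numbers of genes the cause was not tested. The other counts lay between 44 and 57. Leaving out barcodes of both lineages kept 21 of 139 T and NK cells in replicate 1 and 31 of 471 in replicate 2 and selects them for a lack of phagocyte RNA. Metabolic and chromatin genes past the threshold went from 0 to 1 with both lineages left out and to 3 with only the 2 classes. The fit of only the 2 classes leaves 1 residual degree of freedom, so its calls are not on a par with those of the main fit.

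The 12 called genes named kept their direction in every setting in which they had a value. They were chosen for the same direction in both libraries, so leaving out a replicate could not turn one. The subtraction of the phagocyte profile cannot turn one within a library either. Not all 12 were tested in each setting. Only 3 were with both lineages left out, 4 in cells with a Cd8a or Cd8b1 UMI and 11 under the looser cell filter. DESeq2's Wald test ended the calls of Ptpn22, Axl, Mfsd1, Cd63, Asah1 and Dab2, and the fit without the block ended these and those of Sh2d2a, Gimap6 and Mpeg1. Calls also ended for Mfsd1, Asah1 and Dab2 in thinned cells, for Cd63, Asah1 and Dab2 in cells with a Cd8a or Cd8b1 UMI, for Dab2 with DESeq2 size factors and for Asah1 with no filter, and the cause was not tested. Over the alternatives the edgeR or DESeq2 adjusted p ran from 0.000247 to 0.390 for Ptpn22, 0.00279 to 0.644 for Axl, 0.00792 to 0.602 for Mfsd1, 0.00127 to 0.779 for Cd63, 0.0215 to 0.793 for Asah1, 0.0101 to 0.720 for Dab2 and 0.00102 to 0.515 for Mpeg1. With the phagocyte profile subtracted, 21 of 28 named genes moved. Over 28 named genes and 334 alternative values, 269 stayed alike, 36 moved, 23 lost and 1 gained significance, and 5 changed sign. A move in size was counted only where a replicate was left out or the phagocyte profile was subtracted. In settings with a test, alike means an unchanged call and sign, not a similar size. Dab2 counts as alike at -2.96 with both lineages left out, against -1.10 in the main fit. Without replicates in turn, Acly ran from -0.15 to 0.94, Ep300 from -0.045 to 0.81, Baz1a from -0.021 to 0.52, Kat2a from 0.16 to 1.68, Slc16a1 from 0.79 to 2.03, Acss2 from 0.14 to 1.07, Kdm6b from -2.01 to -0.71, Fabp5 from -1.43 to -0.38, Slc43a2 from -1.64 to -0.80, Gpi1 from -0.65 to -0.20 and Srebf2 from 0.22 to 0.45. Thinned to 1500 UMIs, Acly was -0.34 and Ep300 -0.27, and the cause was not tested. Leaving out a replicate gives folds and no test.

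With ComBat by library, where clusters were also named by rule and not by hand, some mean shares moved. They were 28.3% for macrophage-like, 5.08% for monocyte-like, 8.16% for type 2 and 1.16% for mature dendritic cell-like cells. Other cell filters moved no mean share by over 1 SD. T and NK groups with 20 or more cells in both libraries numbered 1, against 2 with the lists allowed in clustering, 2 at resolution 0.6 and 0 at resolution 1.5. Over all genes detected in both libraries, Pearson r was 0.945 for phagocytes, 0.876 for T and NK cells and 0.899 for Ptprc-low cells. The alternatives planned for exhausted states and for CD4 T cells were not run, because those comparisons were not made. Depth limits genes of a few CPM, Acss2 and Slc16a1 among them.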

Other observations

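In this part, all comparisons of other classes with phagocytes, and all tests except that of phagocytes as 1 source of RNA, were chosen only after the result was seen. The cluster led by Mgl2 and Napsa, called type 2 dendritic cell-like, held more RNA of H2-DMa and less of Maf than phagocytes. Its name is uncertain, since its top 10 genes held 0 of its own markers and 1 of monocytes, Ccr2. Of the genes outside the clustering set, edgeR called 36 higher and 42 lower. H2-DMa, which helps load peptides on class II molecules, stood at 931 ± 10.1 CPM against 577 ± 178, a log2 fold change of 0.94 (SE 0.24, edgeR adjusted p = 0.0184). Maf, a transcription factor of macrophages (77.5 ± 11.1 against 389 ± 7.37 CPM), had a log2 fold change of -2.16 (SE 0.31, edgeR adjusted p = 9.17e-05). Listed genes that fell were Fabp5, by 1.99 (edgeR adjusted p = 0.00732), and the glycolytic enzymes Aldoa and Pkm, by 0.84 and 0.86 (0.0175 and 0.0340). Among the 14 glycolysis genes the camera adjusted p was 0.122, and the adjusted p was 0.707 with an estimated correlation. C1q RNA in these barcodes stood at 15.5% and 47.6% of the phagocyte level.

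C1q RNA stood at 66.7% and 79.3% of the phagocyte level in mature migratory dendritic cell-like barcodes, 37.1% and 52.8% in plasmacytoid and 71.7% and 76.0% in neutrophil-like barcodes. Mature migratory dendritic cell-like cells (24 and 26 cells) had 21 genes higher and 0 lower in edgeR, with 154 at an unadjusted p under 0.05 and no other tool run. Ly75, an endocytic receptor of dendritic cells, rose by 4.96 (SE 1.03, edgeR adjusted p = 0.0109) and Ramp3, a receptor activity-modifying protein, by 5.08 (SE 0.79, edgeR adjusted p = 0.000349). Ly75 stood at 95.5 ± 6.23 against 2.90 ± 0.210 CPM and Ramp3 at 259 ± 84.2 against 7.84 ± 3.97. A count of 3 is worth 68.3 and 59.9 CPM in this class, so the Ly75 level rests on a few UMIs per library. Plasmacytoid dendritic cell-like cells (29 and 23 cells) had 11 genes higher and 5 lower. Fdps, an enzyme of the mevalonate pathway, stood at 245 ± 27.4 CPM against 52.0 ± 16.5 there, a rise of 2.17 (SE 0.46, edgeR adjusted p = 0.00974). Their glycolysis genes had a median log2 fold change of -0.56 with a camera adjusted p of 0.00976, lost with an estimated correlation (adjusted p = 0.587). Neutrophil-like cells (25 and 146 cells) had 0 such genes past the threshold in edgeR, with 61 at an unadjusted p under 0.05 and no other tool run. Their dissociation stress genes had a camera adjusted p of 0.0011, lost with an estimated correlation (adjusted p = 0.680).

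Lyz2 (chromosome 10, 117277331 to 117282321) was 255-fold higher in phagocytes of replicate 1 than of replicate 2 (interval 185 to 362, from 15658 and 37 UMIs), while its neighbour Lyz1 stood at 11.9 CPM in replicate 1 and 351 CPM in replicate 2. Reads exchanged between the 2 genes were argued against, since their summed CPM still differed 18.9-fold. So was a lack of macrophages and monocytes together, whose markers had a median of 112% of their level in replicate 1. Macrophage markers ran from 22.4% for Apoe to 149% for Adgre1 and monocyte markers from 48.6% for Fn1 to 680% for Vcan, so the mix within the phagocytes can differ. Whether Lyz2 RNA was lost outside phagocytes cannot be told apart from loss in phagocytes alone. The Lyz2 level of the 6 other classes in replicate 1, as a percent of phagocytes, was at most 1.82 times their C1q percent. The 2.06-fold quartile spread given below for T and NK barcodes can include genes that those cells express, so it does not bound this ratio. The bound of 2 times for RNA of their own was set with these values in view. The labels name no strain or Lyz2 allele, and no biological explanation was tested.

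Phagocyte RNA stood high in T and NK barcodes, with C1q RNA at 35.6% and 64.0% of the phagocyte level. Free RNA alike in all droplets was argued against, since the C1q level was 14.9-fold higher in T and NK barcodes than in Ptprc-low barcodes of replicate 1 and 64.9-fold higher in replicate 2. Phagocytes of the same library as 1 source cannot be told apart from several sources. The ratio of upper to lower quartile over abundant phagocyte genes was 2.06 in replicate 1, between the bounds of 2 and 3 set for either outcome. It was 1.30 in replicate 2, under the lower bound, where 1 source needed both libraries under it. These genes were not screened for expression by T and NK cells themselves, and their median ratios of 50.3% and 73.1% lay above the C1q levels. The spread therefore cannot decide the question. C1qa also ran from 581 to 2435 CPM between T and NK groups mostly of replicate 2, so phagocyte RNA was not alike in all T and NK barcodes. Cells sorted or captured together could give this, and no biological explanation was tested.

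Xist, the RNA of the inactive X chromosome, stood at 581 CPM in phagocytes of replicate 1 and had 0 UMIs in replicate 2, where the limit is 2.28 CPM. Y-linked genes stood at 113 CPM in phagocytes of replicate 2 and had 0 UMIs in replicate 1, with a limit of 1.37 CPM. Among T and NK cells, Ncr1, an NK cell receptor gene, stood at 99.1 CPM in replicate 1 and 6.24 in replicate 2, and the granzyme genes Gzmd and Gzmg at 4.13 and 12.4 CPM in replicate 1 and 121 and 199.8 CPM in replicate 2, where shared reads among close granzyme copies make each value uncertain. Gm42418, a gene that overlaps ribosomal RNA, took 10.2% of the UMIs of replicate 1 and 3.94% of those of replicate 2.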
